A study of Homo sapiens with 3 samples.

How the data were processed

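Gene expression was measured in HepG2 cells, an established human liver tumour line, 72 h after transfection with RNA interference duplexes. A biotin-labelled array was made from total RNA of each of 3 transfections. These used a low-GC control duplex, NOTUM duplex 1 and NOTUM duplex 2, so there is 1 array per group. The arrays were labelled by an Affymetrix protocol and held 54675 probe sets, of which 62 are control probe sets. Nothing in the labels says that any transfection was repeated, and no replicate was analysed here.

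The deposited values are intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version, the chip definition and a genome build are not given in the sources used here, and no genomic coordinates are reported for that reason. On each array the mean of the deposited intensities without the lowest and highest 2% of probe sets was 100.01, so the values had been scaled to a common target of 100 before deposition. Detection calls were not used here. Of the 54675 probe sets, 41097 carried exactly 1 gene symbol, 1801 carried several and 11777 carried none in the table used here. Of those with 1 symbol, 41043 were matched by gene ID to a RefSeq gene table of GRCh38.p14, used for names only, and no symbol changed. Only probe sets with 1 symbol were named or counted, and the others were not analysed here. Of the 727 different genes in the gene lists, 653 had such a probe set.

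The values were used as deposited and converted to log2 with no pseudocount. A single value of 0 was set to the lowest positive value of its array. Control probe sets were left out. A probe set entered the comparisons if its mean log2 intensity over the 3 arrays reached the median of all probe sets, which corresponded to an intensity of 16.9. Where a gene had several such probe sets, the one with the highest mean was used, which left 11676 genes. The upper quartile of probe sets, with a mean intensity of at least 89.3, held 7492 of these genes.

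With 1 array per group the differences have no replicate check, and no p-value is given for any of them. A gene was counted as higher or lower when it differed by at least 2-fold, with both duplexes in the same direction where both are named. As a measure of scatter, the SD of the log2 difference between the NOTUM arrays was computed over the 500 genes of nearest mean intensity. This SD holds array noise, culture variation and any effect of a single duplex. Both comparisons share the control array. Counts of shared changes were therefore set beside 100 simulations of 3 unchanged arrays with that scatter, beside the overlap of independent lists, and beside the same count with each NOTUM array taken as the array that differs.

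There were 27 gene lists, fixed before the data were examined. Each was described by the median log2 fold change of its measured members and the percentile of that median among 10000 random lists. Random lists had the same size and were drawn within 150 ranks of mean intensity of each member. A list was called only when its percentile was below 1 or above 99 with both duplexes. The matching of random lists at the highest intensities was corrected after seeing the data, because the brightest gene had been drawn repeatedly. Before that correction the ribosomal protein list was also called. Random draws treat genes as independent, so percentiles describe these arrays and not the variation between cultures. In 100 simulations of unchanged arrays, a mean of 0.02 of the 27 lists was called. The noise of each gene was drawn independently there. The simulations therefore cannot show how often a list is called when its genes vary together between cultures.

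The genes named were chosen by a rule fixed before the data were examined. They are NOTUM, the 12 genes higher and 12 lower with the largest smaller-of-both change, the 5 genes each way with the largest difference between the duplexes, and up to 4 members per list. Because most of the genes ranked first were dim, the same ranking within the upper quartile was added after seeing the data. Genes named outside these rules are marked as chosen after their values were seen.

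Alternatives were quantile normalization, centring on array medians, pseudocounts of 16 and 64, no intensity filter, the upper quartile, fold thresholds of 1.5 and 3, the mean of a gene's probe sets, and exclusion of probe sets whose names end in _x_at or _s_at. The excluded probe sets are called cross-hybridising, or marked as cross-hybridising, in what follows. The suffix _s_at can also mark probes shared by transcripts of 1 gene, so changes under this setting need not come from cross-hybridisation. Each duplex alone and limma with the duplexes taken as 2 samples of a single group were also run. On simulated data with this scatter, the 2-fold rule recovered 34% of genes changed by 2-fold, 82% of those changed by 3-fold and 96% of those changed by 4-fold, each out of 50 among 11676 genes. It also called 306 of 11476 unchanged genes. The list rule called 15 of 20 lists of 30 genes shifted by 0.4 on the log2 scale and 0 of 20 unshifted lists, whereas an earlier run with another random seed called 1 shifted list fewer and 1 unshifted list more. In these simulations too, noise was drawn independently for each gene. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.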

Results

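Expression was compared between HepG2 cells transfected with a control duplex and cells transfected with either of 2 duplexes against NOTUM. NOTUM encodes a secreted carboxylesterase that inactivates Wnt ligands by removing their lipid group. The stated aim in the labels was to find genes downstream of NOTUM. Each of the 3 conditions was represented by 1 array, so precision is limited by the number of arrays. The median intensity was 18.9 on the control array, 19.1 on the duplex 1 array and 19.9 on the duplex 2 array. Across the 11676 genes compared, log2 intensities correlated at 0.965 between control and duplex 1, at 0.960 between control and duplex 2 and at 0.953 between the duplexes. These correlations are across genes, which are not independent replicates. The 3' to 5' intensity ratio of the GAPDH control probe sets was 1.01 on the control array, 1.03 with duplex 1 and 1.07 with duplex 2. For ACTB the ratios were 1.45, 1.43 and 1.62 in the same order.

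NOTUM itself was measured by a single probe set. Its intensity was 697.3 in control cells, 172.1 with duplex 1 and 208.6 with duplex 2. This is 4.05-fold lower with duplex 1 and 3.34-fold lower with duplex 2. The log2 fold changes were -2.02 and -1.74, against an SD of 0.50 for the difference between the duplex arrays among genes of like intensity. The difference of 0.28 between the duplexes was smaller than that SD.

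IGFBP1, LCN15, DKK1, CEMIP, MATN3, RNASEH2A and CHST15 were at least 2-fold lower with both duplexes. IGFBP1, a liver-derived protein that binds insulin-like growth factors, went from an intensity of 994.4 to 216.5 with duplex 1 and 220.6 with duplex 2, with log2 fold changes of -2.20 and -2.17. LCN15, a lipocalin, went from 374.1 to 85.6 and 57.0. DKK1, a secreted inhibitor of Wnt signalling and a Wnt target, went from 196.7 to 76.6 and 75.5, which is 2.57-fold and 2.61-fold lower. CEMIP, a protein that takes part in hyaluronan breakdown, was 5.74-fold lower with duplex 1 and 2.37-fold lower with duplex 2. The matrix protein gene MATN3 was 4.58-fold and 2.81-fold lower. RNASEH2A, the catalytic subunit of a ribonuclease H, was 2.70-fold and 3.02-fold lower, and the sulfotransferase gene CHST15 was 2.62-fold and 2.37-fold lower.

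In the other direction, AKR1D1, a steroid reductase of bile acid synthesis, had intensities of 130.5 in control cells, 531.7 with duplex 1 and 331.7 with duplex 2. HPD, an enzyme of tyrosine breakdown, was 2.01-fold higher with each duplex, from a control intensity of 1156.6. ZMAT3, a p53 target, was 2.37-fold higher with duplex 1 and 5.28-fold higher with duplex 2, and all 4 of its other probe sets were at least 2-fold higher with each duplex. TP53INP2 was 2.39-fold and 2.96-fold higher, and RAB21 was 2.15-fold and 2.02-fold higher. HMGCS1, the cytosolic synthase of the mevalonate pathway, had log2 fold changes of 1.58 and 1.83. Its other probe set gave 1.22 with duplex 1 but -0.76 with duplex 2. SMAD3-DT was 3.74-fold and 2.42-fold higher. TTC39C, SGTB, CACUL1, NHLRC3 and APOL6 also ranked among the 12 higher genes, but at least 1 other probe set of TTC39C, SGTB, NHLRC3 and APOL6 had the opposite sign with a duplex. Other probe sets of CACUL1 had the same sign. The remaining lower genes of the upper quartile were NAALAD2, for which another probe set gave 0.25 with duplex 2, the ribosomal pseudogene RPL23AP32, whose probes can share transcripts with the parent gene, and SMAD9, TM4SF5 and SUSD1, whose log2 fold changes lay between -1.17 and -0.99.

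The planned ranking over all 11676 genes was led by dim probe sets. The 12 genes with the largest increase were IL37, ADAMTS10, RELT, NEBL, CNTROB, KBTBD4, COL11A2, ATOH8, SPRED3, SLC67A1-AS, SELENON and CD53. Their control intensities were between 4.5 and 10.1, and their intensities with the duplexes were between 28.1 and 82.5. The other probe set of KBTBD4 gave -1.19 with duplex 2. Among the 12 genes with the largest decrease, CORO1A, PIMREG, MBLAC1, LINC01504, LOC374443, MMP28 and PRDM16-DT had control intensities between 36.2 and 68.7. At such intensities the SD of the difference between the duplex arrays was between 0.76 and 0.98.

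With both duplexes 136 genes were at least 2-fold higher and 57 at least 2-fold lower, of which 11 and 9 belonged to the upper quartile. Simulated unchanged arrays with a shared control gave a mean of 341.4 such genes, with a range of 302 to 377, and 96.4 in the upper quartile, more than the 193 and 20 observed. The simulated scatter includes any effect of a single duplex, so it can be too large. Overlap of independent lists would give 13.2 higher and 15.9 lower genes. When the duplex 1 array was taken as the array that differs, 310 genes were at least 2-fold away from both others, and with the duplex 2 array 355 genes. Simulated arrays gave more calls than were observed, so the whole excess over independent lists can come from the shared control. The count was lowest with the control array as the array that differs, and it does not exceed what array scatter gives. It therefore gives no evidence of a response shared by the duplexes. Because the simulated scatter can be too large, the count does not exclude such a response either. The log2 fold changes of the duplexes correlated at 0.37 across genes, against 0.50 in the simulation, and their covariance was 0.113 against 0.189.

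**Figure D1:**
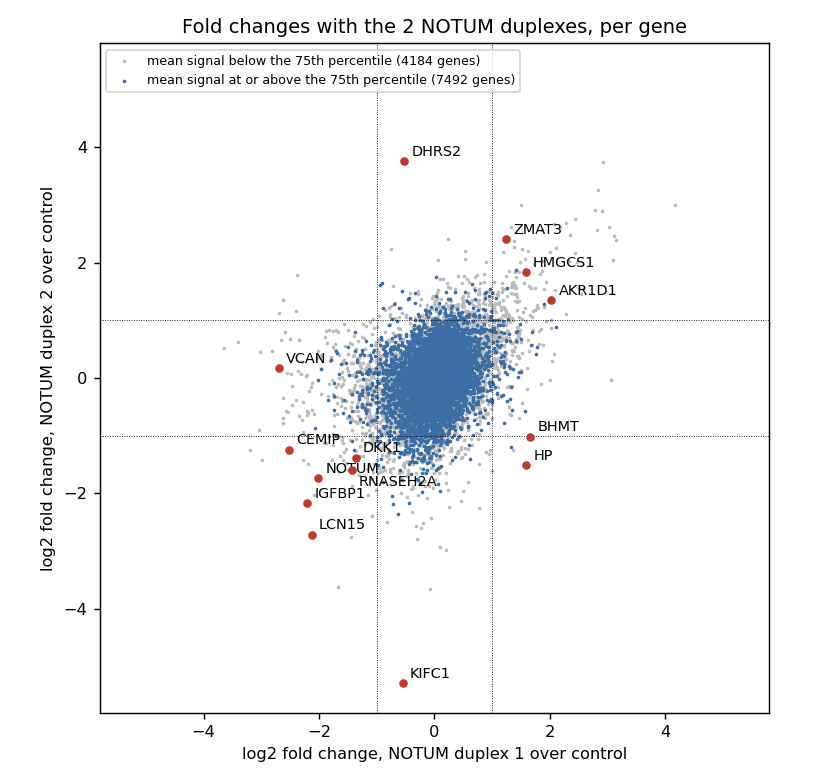
Each point is 1 of the 11676 genes, with the log2 fold change over control for NOTUM duplex 1 on the x axis and for NOTUM duplex 2 on the y axis. Blue marks genes in the upper quartile of intensity, grey the rest, red the labelled genes, and dotted lines 2-fold change. NOTUM, IGFBP1, LCN15 and DKK1 lie at least 2-fold below control with both duplexes, whereas HP and BHMT lie on opposite sides.

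Genes of the cell cycle were lower with both duplexes, and more so with duplex 2. The mitosis list, with 32 of 32 genes measured, had a median log2 fold change of -0.28 with duplex 1 and -1.01 with duplex 2. The DNA replication list, with 30 of 31 measured, had medians of -0.29 and -0.88. All 4 medians lay below those of all 10000 random lists. Of the 62 genes, 51 were below control with both duplexes and 61 were lower with duplex 2 than with duplex 1. No gene of either list was 2-fold lower with duplex 1, and 28 were with duplex 2. Examples are the mitotic kinase AURKB, at -0.71 with duplex 1 and -1.57 with duplex 2, the mitotic kinesins KIF11, at -0.59 and -1.30, and KIF23, at -0.79 and -1.41 with another, dimmer probe set at -0.27 and -0.30, and the replication genes CDC45, at -0.63 and -2.36, and RRM2, at -0.60 and -1.59. The duplex 2 array was also the array with the highest 3' to 5' ratios for GAPDH and ACTB.

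**Figure D2:**
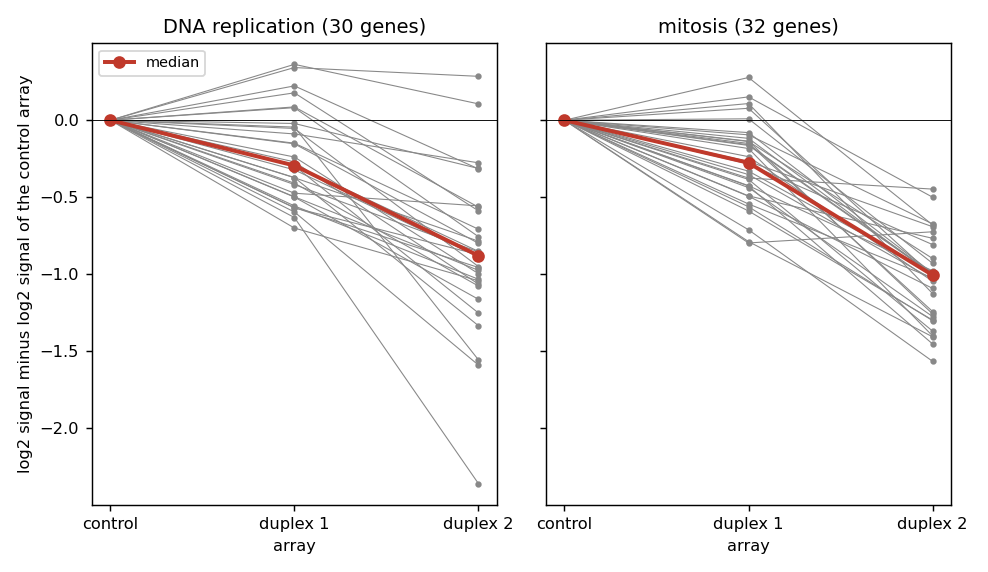
Log2 intensity minus that of the control array on the y axis, for the control, duplex 1 and duplex 2 arrays on the x axis. Each grey line joins the values of 1 gene of DNA replication (left, 30 genes) or mitosis (right, 32 genes) and the red line joins the medians, which reach -0.88 and -1.01 with duplex 2.

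Genes of lipid synthesis were higher with both duplexes than on the only control array. A deviation of that control culture alone cannot be told apart from an effect of silencing here. The cholesterol synthesis list, with 18 of 25 genes measured, had medians of 0.39 with duplex 1 and 0.26 with duplex 2, at percentiles of 100 and 99.55. The median with duplex 2 was 0.18 after median centring and 0.44 without probe sets marked as cross-hybridising, where that with duplex 1 was 0.35. In this list 14 genes were above control with both duplexes and 1 was below. Besides HMGCS1, the sterol oxidase gene MSMO1 was at 0.74 and 0.92, the cyclase gene LSS at 0.70 and 1.08, and the isomerase gene IDI1 at 0.75 and 0.58, although 2 dimmer IDI1 probe sets were at -0.49 and -0.43 with duplex 1. Only HMGCS1 was 2-fold higher with both duplexes. Between the duplex arrays the median difference of the cholesterol list was 0.02, at a percentile of 76.7. The fatty acid and triglyceride synthesis list, with 21 of 24 measured, had medians of 0.31 and 0.50, at percentiles of 99.93 and 100. In that list 17 genes were above control with both duplexes and 1 was below, and none was 2-fold higher with both. The elongase gene ELOVL6 was at 0.76 and 1.17, GPAM at 0.90 and 0.56, MLXIPL at 0.80 and 0.91 and SREBF1, a regulator of this pathway, at 0.60 and 0.50. The fatty acid list did not pass with both duplexes when a gene's probe sets were averaged, where its median with duplex 2 was 0.28, at a percentile of 98.9, or when probe sets marked as cross-hybridising were excluded, where its percentile with duplex 1 was 96.3. These 4 lists were the only ones of the 27 called with both duplexes. Both comparisons share the control array, so such a call does not single out a response to NOTUM silencing. Both cell cycle lists also lay below all random lists for duplex 2 against duplex 1. The p53 list, at percentiles of 99.57 and 99.96, and the metallothionein list, at 0.02 and 0.01, likewise set duplex 2 apart from control and from duplex 1.

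With duplex 1 against control, 359 genes were at least 2-fold higher and 405 at least 2-fold lower. Targets of Wnt signalling had a median of -0.34 with duplex 1, at a percentile of 0.01, and of 0.02 with duplex 2, at a percentile of 63.4, over 21 of 31 listed genes. The median with duplex 2 was -0.06 after median centring and 0.17, at a percentile of 88.8, without probe sets marked as cross-hybridising. NOTUM is a member of this list, and without it the medians were -0.34 and 0.07 over 20 genes. Among members chosen after their values were seen, AXIN2 was at -0.55 and -0.35, LGR5 at -0.62 and 0.24, and NKD1 at -0.46 and 1.38. With duplex 2 other probe sets reached -1.43 for AXIN2, and were at -0.01 for LGR5 and at 0.25 and 0.91 for NKD1. DKK4 was at 1.65 and 0.46, and BIRC5, which also acts in mitosis, at -0.36 and -1.45, although another of its probe sets was at 0.18 with duplex 2. Genes for plasma proteins made by hepatocytes had a median of 0.25 with duplex 1, above all random lists, and of -0.13 with duplex 2, at a percentile of 54.7, over 39 of 45 genes. The median with duplex 2 was 0.00 after quantile normalization, -0.20 after median centring and 0.03 without probe sets marked as cross-hybridising, so no direction is given for it. FGA, a fibrinogen chain, was at 1.13 and 0.91, whereas FGB, SERPINC1 and KNG1, chosen after their values were seen, were at 1.20, 1.22 and 1.31 with duplex 1 and at 0.39, 0.11 and -0.36 with duplex 2. With duplex 2, another probe set of FGB was at 0.75, another of SERPINC1 at -0.35 and another of KNG1 at 0.30. Fatty acid oxidation genes had a median of 0.31 with duplex 1, at a percentile of 99.96, and 0.04 with duplex 2, or -0.03 after median centring, over 18 of 25 genes, with HADHA at 0.33 and 0.38 and CPT1A at 0.56 and 1.34. With duplex 2, the other probe sets of CPT1A were at 0.09 and 0.17. Without probe sets marked as cross-hybridising the percentile with duplex 1 was 98.9. The list of matrix genes and TGF-beta and YAP targets had a median of -0.18 with duplex 1, at a percentile of 0.73, and 0.05 with duplex 2, or -0.02 after median centring, over 30 of 37 genes. Its percentile with duplex 1 was 3.26 without probe sets marked as cross-hybridising and 1.40 and 1.77 with pseudocounts of 16 and 64. In that list CCN1 was at -2.63 and -0.79 and CCN2 at -2.07 and -0.87.

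With duplex 2 against control, 429 genes were at least 2-fold higher and 458 at least 2-fold lower, and 342 and 580 after centring on array medians. Genes of the p53 response had a median of 0.30 with duplex 2, at a percentile of 99.57, and -0.13 with duplex 1, at a percentile of 4.56, over 25 of 29 genes. The percentile with duplex 2 was 98.5 without probe sets marked as cross-hybridising and 98.8, with a median of 0.17, with a pseudocount of 64. In the upper quartile the medians were -0.27 with duplex 1, at a percentile of 0.18, and 0.24 with duplex 2, at a percentile of 98.4. RRM2B was at 0.68 with duplex 1 and 1.08 with duplex 2 and MDM2 at -0.58 and -0.80, but the 8 other probe sets of MDM2 went both ways and reached 1.41 with duplex 2. The cell cycle inhibitor gene CDKN1A, chosen after its values were seen, was at -0.44 and 1.38. The metallothionein list had a median of -0.59 with duplex 2, at a percentile of 0.02, and 0.21 with duplex 1, at a percentile of 97.4, over 12 of 16 genes. All 7 measured members of the MT1 and MT2 families were below control with duplex 2, at between -0.996 and -0.56, including MT1X at -0.996 and MT2A at -0.94. These paralogs are close in sequence, so their probe sets do not measure them independently, and all 7 are marked as cross-hybridising. Without such probe sets the list kept 5 genes and none of these 7, with medians of 0.76 with duplex 1, at a percentile of 99.86, and -0.04 with duplex 2, at a percentile of 41.7. Heat shock genes had medians of 0.16 and 0.24, at percentiles of 96.8 and 99.76, with HSPH1 at 0.55 and 0.85. Without probe sets marked as cross-hybridising these medians were 0.35 and 0.83, at percentiles of 99.02 and 99.99. Genes of the unfolded protein and amino acid responses had medians of 0.09 and 0.15, at percentiles of 86.7 and 99.42, the latter 98.2 after quantile normalization, 98.9 in the upper quartile and 85.8 without probe sets marked as cross-hybridising, with DNAJB9 at 0.61 and 0.56.

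**Figure D3:**
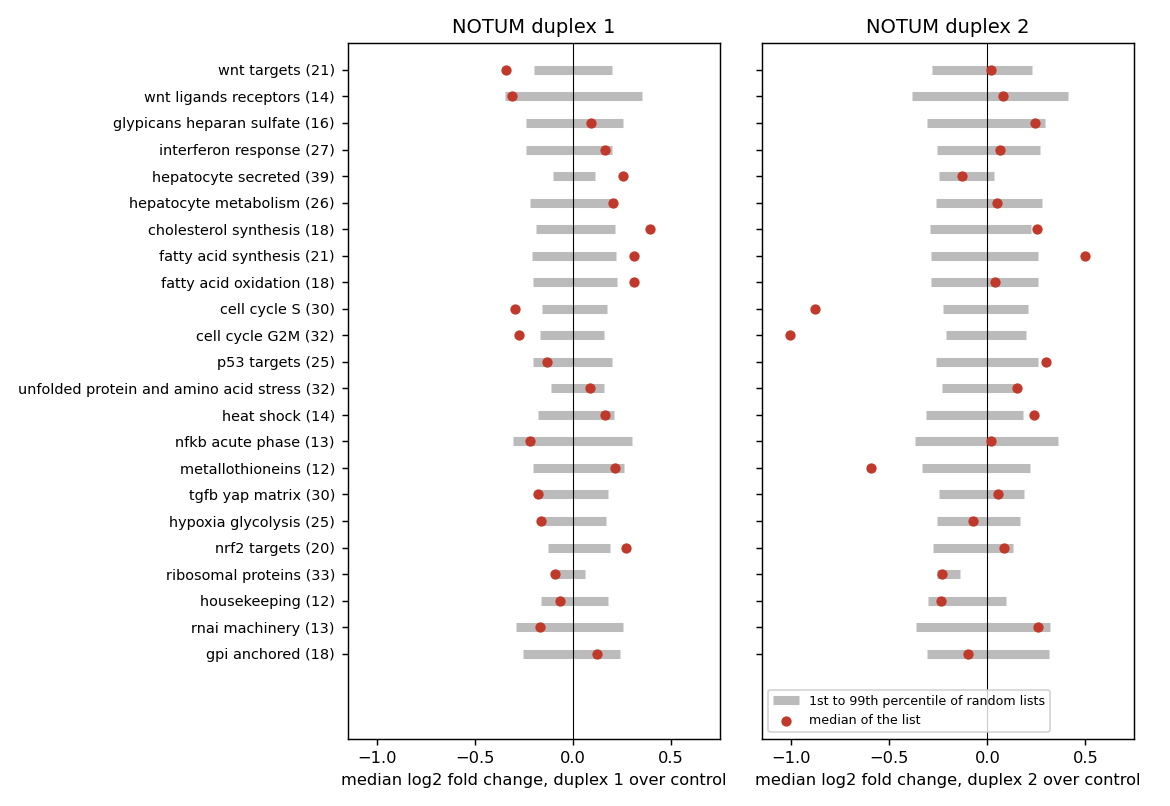
Median log2 fold change over control (x axis) of each gene list with at least 10 measured genes (y axis, number of genes in brackets) with duplex 1 (left) and duplex 2 (right). Grey bars span the 1st to 99th percentile of 10000 random lists of the same size and intensity, and the red points of cholesterol synthesis, fatty acid synthesis and both cell cycle lists lie outside the bars on the same side in both panels.

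Between the duplex arrays, 585 genes were at least 2-fold higher with duplex 2 and 502 at least 2-fold lower, of which 205 and 218 belonged to the upper quartile. The balance depended on the scaling, since the share that was higher was 53.8% as reported, 46.9% after quantile normalization and 45.3% after median centring. HP, which encodes haptoglobin, had an intensity of 1151 in control cells, 3480 with duplex 1 and 404.4 with duplex 2. BHMT, a methyltransferase of homocysteine metabolism, was at 169.9, 536.7 and 83.8, and HAMP, which encodes hepcidin, at 639.9, 1903 and 432.9. HPR is close in sequence to HP and had values of 186.4, 468.1 and 81.0. KIFC1, a mitotic kinesin, was 1.47-fold lower with duplex 1 and 39.0-fold lower with duplex 2, where its intensity of 3.8 was too low for an exact fold. DHRS2, a short-chain dehydrogenase, went the other way, from 33.3 in control cells to 23.2 with duplex 1 and 449.4 with duplex 2, and its other probe set was at 0.94 with duplex 1 and 3.17 with duplex 2 on the log2 scale. VCAN, the proteoglycan versican, had intensities of 473.0, 72.8 and 532.4, and all 4 of its other probe sets were at least 2-fold lower with duplex 1. TSPO was at 116.9, 62.4 and 367.0, RBM24 at 146.0, 76.1 and 443.6, ICAM1 at 215.5, 83.5 and 373.9, with another probe set at 0.04 with duplex 1, CNOT6 at 245.9, 75.8 and 338.2, with another probe set at -0.11 with duplex 2, and ISOC1 at 629.9, 674.8 and 161.2. The other genes in the planned ranking, MEF2D, HLA-DOA, SLC22A7, INA, DUSP4, TEX19 and TAC3, had control intensities between 23.9 and 46.6. The mitosis list was lower with duplex 2 than with duplex 1 by a median of -0.79, the DNA replication list by -0.56, the metallothionein list by -0.81 and the plasma protein list by -0.35. Random lists of like intensity had medians of -0.01, -0.03, -0.10 and -0.13 in the same order. The p53 list was higher by 0.41, the small RNA machinery list by 0.51 and the list of matrix genes by 0.25. In all, 7 of the 27 lists lay outside the 1st to 99th percentile of random lists in this comparison. The counts over control were 10 for duplex 1 and 8 for duplex 2. Independent genes would give 0.54 in each, but genes of a list can vary together between cultures. Arrays that share the silenced gene already gave 7, so these counts do not separate an effect of NOTUM silencing from variation between arrays.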

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

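In this part, the tests of scaling were set before their results were seen, and those of the control array, of the depth of silencing and of dim probe sets were chosen after the results were seen.

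HP, which encodes haptoglobin, BHMT, HPR, INA and TAC3 were at least 2-fold away from control in opposite directions with the 2 duplexes, and these differences were not tested because each condition has 1 array. The log2 difference, duplex 2 minus duplex 1, was -3.11 for HP, -2.68 for BHMT and -2.53 for HPR. It was 4.17 for INA and 3.97 for TAC3, but their intensities with duplex 1, 4.6 and 7.1, were too low for an exact difference.

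Genes of mitosis and DNA replication were lower with both duplexes and more with duplex 2. Scaling between arrays is argued against, since the mitosis median with duplex 2 was -1.03 after quantile normalization. A control array that alone stands apart is argued against for the larger part with duplex 2, since the duplex arrays differed from each other by a median of -0.79. It stays open for the smaller part, because the median of -0.28 with duplex 1 cannot be told apart from a deviation of the only control culture. Deeper silencing by duplex 2 also stays open, since NOTUM was higher with duplex 2 by 0.28, within the SD of 0.50, and a biological effect of losing NOTUM or of a single duplex on other transcripts was not tested.

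Metallothionein genes were lower with duplex 2 than with duplex 1 by a median of -0.81. Scaling between arrays is argued against as the whole cause, since the median was -0.70 after quantile normalization. The MT1 and MT2 genes had only probe sets marked as cross-hybridising, and without them 5 other genes of the list remained, with a median difference of -0.64. Their medians were 0.76 with duplex 1 and -0.04 with duplex 2, but these come from different genes. The median difference was that of SLC39A14, at 0.35 with duplex 1 and -0.30 with duplex 2. SLC30A10, at 2.01 and -0.04, and MT3, at 1.61 and 0.18, were lower with duplex 2 than with duplex 1. MTF1, at -0.27 and -0.11, and SLC30A1, at 0.76 and 0.84, were not. Shared transcripts among the paralogs, a difference between cultures and an effect of either duplex stay open and were not tested.

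Among genes that were 2-fold away from control with both duplexes, 70.5% were higher. Noise of dim probe sets was tested as an explanation and stays open. In its favour, 55% were higher in the upper quartile, but this share rests on 20 genes. Against it, genes 2-fold away from the duplex 1 array or from the duplex 2 array were still mostly higher in the other arrays within the upper quartile, at 64.4% and 69.3%, compared with 75.2% and 63.1% over all genes. Most genes were thus higher in the other arrays whichever array was taken as the one that differs. The excess of higher genes is therefore not particular to the comparison with control. Scaling also bears on the share, which was 61.5% after median centring. The share was 72.1% with a pseudocount of 16, 33.3% of only 9 genes with a pseudocount of 64, and 82.9% at 3-fold. A biological explanation was not tested.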

How the results depend on the processing

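Exclusion of cross-hybridising probe sets for lists, and the ranking of named genes within the upper quartile, were chosen after seeing the data. The counts rested on the intensity filter, the pseudocount and the fold threshold. The counts that follow are genes higher and lower together, for duplex 1, duplex 2, both duplexes and duplex 2 against duplex 1 in this order. They were 764, 887, 193 and 1087 as reported, 346, 412, 61 and 578 with a pseudocount of 16, and 92, 102, 9 and 185 with a pseudocount of 64. They were 5126, 5075, 2381 and 5321 with no filter on dim probe sets, 187, 294, 20 and 423 in the upper quartile, 2327, 2860, 799 and 3228 at 1.5-fold, and 188, 166, 35 and 249 at 3-fold. Requiring a single duplex in place of both gave 764 genes for duplex 1 and 887 for duplex 2. Quantile normalization, median centring, averaged probe sets and exclusion of cross-hybridising probe sets each kept every total within 1.5 times. The genes behind the totals changed more. Of the 185 genes called with both duplexes after quantile normalization, 176 were among the 193. This held for 172 of 187 after median centring and 168 of 183 with averaged probe sets. It held for 147 of 181 without cross-hybridising probe sets and 43 of 61 with a pseudocount of 16. With the duplexes as 2 samples of a single group and the lone control assumed to vary like them, limma called 0 genes at an adjusted p under 0.05 and 249 at an unadjusted p under 0.05, whereas the same fit with the duplex 1 array as the lone array called 49 and 717, and with the duplex 2 array 0 and 1272. The correlation between the duplexes was 0.37 as reported, 0.35 and 0.32 with pseudocounts of 16 and 64, 0.50 with no filter and 0.30 in the upper quartile. Fold changes of NOTUM moved by less than the SD of 0.50 under every scaling and pseudocount tried. Both cell cycle lists and the cholesterol list were called under all 8 alternatives run for lists. Fatty acid synthesis was lost when a gene's probe sets were averaged, which left 3 lists, and when cross-hybridising probe sets were excluded, which gained heat shock genes. In the upper quartile the same 4 lists were called, and no gene of the fibroblast list was left to measure. Single genes were checked only where the rankings named them, apart from NOTUM. Genes named only as list members, or chosen after their values were seen, were not part of this check. Among checked values of at least 2-fold, only that of APOL6 with duplex 1 changed sign. It went to -0.30 when its probe sets were averaged, because its 3 other probe sets were lower. Of the 124 values checked, 33 moved by more than their SD with a pseudocount of 16, 56 with 64 and 13 with averaged probe sets. The cause of the changed counts was not tested. Leaving out replicates was not possible with 1 array per group. No paired analysis was possible because each group has 1 array. Low intensity limits precision, since the SD between the duplex arrays was 0.98 for the dim gene SPRED3 and 0.48 for IGFBP1.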

Other observations

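Further lists are given here, none of which was called with both duplexes. Targets of the oxidative stress regulator NRF2 had medians of 0.27 with duplex 1, at a percentile of 99.99, and 0.09 with duplex 2, at a percentile of 96.8. The median with duplex 2 was 0.01 after median centring, 0.02 with averaged probe sets and 0.19 without probe sets marked as cross-hybridising. In that list HMOX1 was at 0.98 and 1.08, AKR1B10 at 1.41 and 0.63 and GCLM, a subunit of the enzyme that makes a glutathione precursor, at 0.48 and 1.14. The list of interferon-stimulated genes and sensors of double-stranded RNA had medians of 0.16 and 0.06, the latter -0.01 after median centring, over 27 genes, at percentiles of 97.2 and 68.6, and no member was 2-fold away from control with both duplexes. In it ISG15 was at 0.69 and 0.56, IFIT3 at 0.89 and 0.57 and OAS1 at -0.63 and -0.72, whereas the other probe set of OAS1 was at 0.39 and 0.99. The NF-kappaB and acute phase list had medians of -0.22 and 0.02, the latter -0.06 after median centring, but 0.24 and -0.22 without probe sets marked as cross-hybridising and -0.03 with duplex 1 when probe sets were averaged, so no direction is given. Its member CCL20 was at -1.77 and -1.42. Hypoxia and glycolysis genes had medians of -0.16, at a percentile of 0.92, and -0.07, or -0.34 and 0.06 without probe sets marked as cross-hybridising. The percentile with duplex 1 was 4.84 with averaged probe sets, 1.23 with no intensity filter and 1.32 in the upper quartile. In that list NDRG1 was at -0.78 and -0.59, whereas HK2 was at 0.58 and 0.79. Dimmer probe sets of HK2 were at -3.14 and -0.53 with duplex 2. Wnt ligands and receptors had medians of -0.31 and 0.08, or -0.05 and 0.30 with averaged probe sets and 0.10 with duplex 1 and no intensity filter. Their percentile with duplex 1 of 1.72 fell to 0.09 with a pseudocount of 64. RYK was at -0.68 and -0.51 and FZD5 at -0.38 and -1.29, with another probe set of FZD5 at -0.11 with duplex 2. The dim genes SFRP4, at 1.14 and 0.96, and WNT10B, at 0.83 and 0.97, went the other way. Glypican and heparan sulfate genes had medians of 0.09 and 0.24, with SDC1 at 0.41 and 0.63 and the dim gene EXTL3 at -0.96 and -0.90.

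The other lists lay within the 1st to 99th percentile of random lists with both duplexes as reported. With averaged probe sets, the percentile with duplex 1 was 99.76 for hepatocyte metabolism, 0.05 for ribosomal proteins and 99.46 for the interferon list, and that with duplex 2 was 99.72 for glypican and heparan sulfate genes. The small RNA machinery list had a median with duplex 2 of 0.09 with averaged probe sets and of 0.53, at a percentile of 99.63, without probe sets marked as cross-hybridising. Medians with duplex 1 and duplex 2 were 0.21 and 0.05, the latter -0.02 after median centring, for hepatocyte metabolism, -0.17 and 0.26 for small RNA machinery, 0.12 and -0.10 for GPI-anchored proteins and -0.07 and -0.24 for genes often used as references. Ribosomal protein genes were at -0.09, at a percentile of 1.00, and -0.23, at a percentile of 23.8, where random lists of like intensity had a median of -0.21 with duplex 2. After quantile normalization the ribosomal medians were -0.03 and -0.003, and that of the reference genes with duplex 2 was -0.07. The reference genes had a median of -0.28 with duplex 1 without probe sets marked as cross-hybridising. Of the markers of other cell types, 2 of 13 fibroblast, 1 of 10 endothelial, 5 of 15 blood cell and 3 of 11 squamous epithelial genes passed the intensity filter, with medians of -1.19, -0.72, -0.29 and -0.02 with duplex 1 and -0.01, 0.27, 0.36 and 0.47 with duplex 2. The endothelial median with duplex 1 was 0.33 when the probe sets of its genes were averaged. With no intensity filter the fibroblast medians were 0.58 and 1.19. Under that setting the endothelial and blood cell medians with duplex 2 were -0.15 and -0.14. The fibroblast and endothelial markers, and the blood cell markers with duplex 2, therefore have no settled direction. The squamous epithelial median with duplex 2 stayed positive in every setting, at 0.26 to 0.81, but rests on few genes.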
